A study of Homo sapiens with 6 samples.

How the data were processed

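The data were 6 bulk RNA-seq libraries of THP1 cells, a human monocytic leukaemia line that is grown in suspension and used as a model of monocytes. Per the labels, RNA was taken from cells in 3 biological replicates with lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria that is sensed by Toll-like receptor 4) at 0.5 µg/ml for 20 h and in 3 without it. Libraries were made in bulk with the Smart-seq2 chemistry, which primes on poly(A) tails and does not mark the strand. The submitters' processing notes name kallisto, a pseudoaligner that assigns reads to transcripts, and the build hg19. The kallisto version and the transcript annotation are not given in the sources used here.

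The authors deposited one table per library with a TPM value (the abundance of transcripts, scaled for their length and for the library's total) for each of 27267 gene symbols. The same symbols stood in all 6 tables, and the values summed to between 995622 and 997187 per library. TPM keeps no read depth, so the depth of each library is unknown and no counting interval or detection floor is given. Because TPM is a share of each library's total, a few abundant transcripts that take a larger share lower the values of all others. A pseudoaligner divides reads between near-identical copies by estimation, so values of CCL3 and CCL3L1, of CCL4 and CCL4L2, of HLA genes, of metallothioneins, of FTH1 and of ribosomal proteins with processed pseudogenes (RPL13A and RPL13AP5) are uncertain. Overlapping and antisense genes cannot be told apart without strand.

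Values were analysed as log2(TPM + 1), which understates the change of genes near 0. Genes with a mean of at least 1 TPM over the 6 libraries were kept, which left 11339. The mean includes the LPS libraries, so a gene low without LPS can pass it through its rise. LPS was compared with no LPS in a linear model with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a prior variance that follows the mean, 4 residual and 4.82 prior degrees of freedom, and Benjamini-Hochberg adjustment over the tested genes. A call is an adjusted p below 0.05, and every adjusted p of a gene is from this test. Log2 differences are LPS minus unstimulated and carry their standard error, and TPM values are means ± SD with n = 3 libraries per group.

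In 29 gene lists fixed before the data were examined, 17 of the 636 symbols had no match in the tables. The 13 mitochondrially encoded mRNAs were among these, and of the mitochondrial transcripts the tables held only the rRNAs RNR1 and RNR2, so that list was not analysed here. The 24 lists with at least 3 tested members were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. None of the 24 lists had an adjusted p below 0.05 with an estimated correlation, where the values ran from 0.185 to 0.976. The named genes are the 12 largest rises and 12 largest falls among called genes without overlap between the groups and with at least 5 TPM in the higher group, then up to 4 called members per list (or the most abundant, where fewer than 2 were called), and a fixed set given whatever its result (TNF, IL1B, IL6, CXCL8, CCL2, CXCL10, CD14, TLR4, LY96, NFKBIA, ACTB, GAPDH). Genes named outside this rule were chosen after their values were seen, and the text says so. Some genes that the rule selects are not reported here.

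The labels number the replicates 1 to 3 in both groups. Deviations from the group means correlated across genes at 0.123, 0.326 and 0.204 for the libraries numbered 1, 2 and 3. All were above 0.1, so a pairing by number was tried. Unstimulated replicate 1 correlated slightly better with LPS replicate 3 (0.172), and unstimulated replicate 3 correlated with LPS replicate 1 at 0.0760. Deviations within a group cancel out for each gene, and unstimulated replicate 2 ran against unstimulated replicates 1 and 3 (-0.689 and -0.824). The 3 correlations are thus not independent. The libraries numbered 2 also held the largest shares of TPM in the 100 most abundant genes (59.0% and 56.8%). These values therefore do not establish that the numbers pair the libraries. The labels do not say that a number marks a shared culture or day. The model without the pairing is the main one, and a model with the replicate number as a block (2 residual degrees of freedom) was run beside it.

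Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter on low values and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of the mitochondrial rRNAs with rescaling, no trend and a robust trend in the prior variance, library weights, the replicate block, and leaving out each library in turn. After the data were examined, 3 more were added: the share of TPM in the 100 most abundant genes as a covariate, the block with median-of-ratios scaling, and that scaling without unstimulated replicate 2. Transcript length and GC content for a check on 1 library came from GENCODE on another genome build, matched by symbol for 95.7% of tested genes, and no coordinates are given. The model was tested on simulated data made from these libraries (11162 genes, 200 changed): it recovered 47.4% of 2-fold and 95.8% of 4-fold changes, with 7.43% of 148 calls false, called the changed list, and called 0 of 200 random lists. The simulated noise was drawn independently for each gene, whereas genes in the real libraries vary together. The simulation therefore does not test the rate of false calls, or the preset correlation of camera, under such shared variation. Figures were drawn with matplotlib 3.10.9.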

Results

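The transcriptome of THP1 cells was measured as bulk poly(A) RNA-seq in 3 unstimulated libraries and in 3 libraries from cells kept with LPS for 20 h, alongside a probe-based single-cell assay of the same cells that is not used here. The comparison asks which transcripts differ after LPS. Between 17239 and 18880 of the 27267 listed genes had a value above 0, and between 10901 and 11428 reached 1 TPM. Read depth is unknown.

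The 3 LPS libraries lay close together, with Pearson correlations across genes of 0.994 to 0.995 on log2(TPM + 1). Unstimulated replicates 1 and 3 correlated at 0.991. Unstimulated replicate 2 stood apart: it correlated with the other two unstimulated libraries at 0.972 and 0.965, and with the LPS libraries at 0.962 to 0.964. Replicates 1 and 3 correlated with the LPS libraries at 0.935 to 0.946. On the first principal component replicate 2 lay at -3.08, between replicates 1 and 3 (-45.2 and -49.0) and the LPS libraries (29.6 to 37.8). Its 100 most abundant genes held 59.0% of the TPM, against 44.3% and 42.7% in unstimulated replicates 1 and 3 and 51.0%, 56.8% and 52.9% in the LPS libraries. The mitochondrial rRNA RNR2 held 9.93% of its TPM, against 4.24% and 4.21% in replicates 1 and 3 and 7.04% to 8.79% with LPS. Its histone genes (symbols opening with HIST) summed to 857 TPM, against 1982 and 3185 in replicates 1 and 3 and 1208, 1234 and 1502 with LPS. LPS-induced cytokine transcripts were low in it, with TNF at 3.50 TPM and IL1B at 0.743 TPM.

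**Figure D1:**
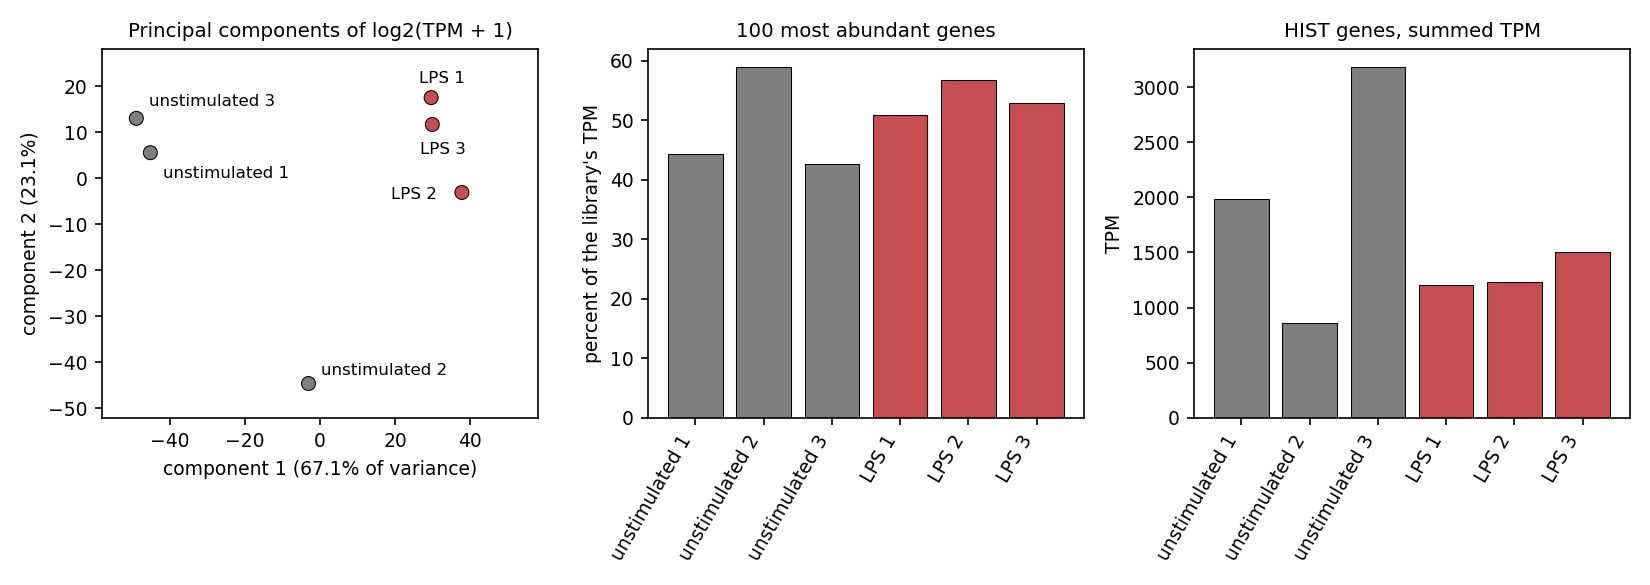
Left, the 6 libraries on the first 2 principal components of log2(TPM + 1), where component 1 holds 67.1% and component 2 holds 23.1% of the variance. Middle and right, bars per library for the percent of TPM in the 100 most abundant genes and for the summed TPM of histone genes, with unstimulated libraries in grey and LPS libraries in red. Unstimulated replicate 2 lies apart from replicates 1 and 3, with 59.0% of its TPM in 100 genes.

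After LPS, 16 of 17 tested chemokines, 6 of 10 tested inflammatory cytokines and 21 of 24 tested NF-kB targets were called higher. As lists they were called by camera with the preset correlation (adjusted p = 1.9e-24, 2.8e-09 and 5.6e-27). Fry called them as well (adjusted p = 0.00016, 0.00018 and 0.00016). They were not called by camera with an estimated correlation (adjusted p = 0.185, 0.261 and 0.185). Among the named genes the largest falls were in SERPINB2, GFI1 and SELPLG. Of 11339 tested genes, 932 were higher and 693 lower with LPS (limma, adjusted p below 0.05), so that 57.4% of the calls were higher. In 744 genes the change was at least 2-fold, 465 of them higher and 279 lower. At this size falls outnumbered rises without unstimulated replicate 2 (567 higher and 1027 lower) and with library weights (550 and 886), and in no other alternative. Median-of-ratios scaling without that replicate gave 897 higher and 438 lower. That scaling with all libraries gave 553 and 207, and the 100-gene share as a covariate 492 and 122. Rises outnumbered falls when any other library was left out: 425 and 89 without unstimulated replicate 1, 468 and 133 without unstimulated replicate 3, and 311 and 90, 412 and 75, and 374 and 118 without LPS replicates 1, 2 and 3. In the main model 101 called genes rose by at least 2 on the log2 scale and 8 fell by as much. These were 104 and 37 without unstimulated replicate 2, and 107 and 33 with library weights. All 3 LPS libraries lay above all 3 unstimulated ones in 2156 genes and below them in 1845, together 35.3% of the tested genes, where chance gives 10%. The median difference over all tested genes was -0.10, and median-of-ratios scaling moved it to 0.00028. Each log2 difference of the main model below thus lies about 0.10 higher relative to the median gene. That median was -0.24 without unstimulated replicate 2 and -0.048 with quantile normalization, so the offset differs for values from those settings.

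The counts of calls, and above all the count of lower genes, moved with the libraries and the scaling. With the replicate block 1326 genes were higher and 1699 lower (43.8% higher), with median-of-ratios scaling 1706 and 1508, and with quantile normalization 1526 and 1901 (44.5% higher). Without unstimulated replicate 2, 2060 of 11394 tested genes were higher and 4769 lower (30.2% higher). The counts of list members given below for that setting stand against these shares over all genes. Standard errors there were 0.092 for ACTB, 0.15 for AZU1 and 0.13 for CANX, against 0.32, 0.44 and 0.29 in the main model. Adjusted p values from that setting lean more on the prior variance shared by genes. Their size is therefore not comparable with that of the main model. Leaving out unstimulated replicate 1 gave 498 higher and 119 lower genes, and leaving out unstimulated replicate 3 gave 613 and 222. Without LPS replicates 1, 2 and 3 in turn, 344, 470 and 415 genes were higher and 107, 99 and 146 were lower. All 1625 calls were also made with the block, and 1585 of them with median-of-ratios scaling and 1623 without unstimulated replicate 2, each with the same sign.

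The CC chemokine genes CCL4 and CCL3, whose products recruit monocytes and lymphocytes, showed some of the largest rises. CCL4 went from 0.146 ± 0.0636 to 195 ± 9.32 TPM (log2 difference 7.42 ± 0.16, adjusted p = 1.0e-07) and CCL3 from 0.802 ± 0.227 to 86.5 ± 7.85 TPM (5.60 ± 0.18). CCL4L2, a near-identical copy of CCL4 that shares reads with it, rose by 6.99 ± 0.19. IL1B, the gene of the fever-inducing cytokine interleukin-1 beta, went from 0.947 ± 0.353 to 163 ± 6.48 TPM (6.41 ± 0.19, adjusted p = 3.6e-07), and TNF from 3.80 ± 0.300 to 185 ± 9.76 TPM (5.28 ± 0.18, adjusted p = 4.8e-07). EBI3, a subunit of interleukin-27 and interleukin-35, rose by 5.14 ± 0.16, and CXCL8, the neutrophil chemoattractant interleukin-8, by 4.96 ± 0.24. ICAM1, a ligand of leukocyte integrins, went from 0.865 ± 0.268 to 113 ± 9.76 TPM (5.94 ± 0.18). Other large rises were in IL4I1, a secreted amino acid oxidase (6.36 ± 0.22), in TNFAIP6, a hyaluronan-binding protein (6.28 ± 0.20), in the antiproliferative gene BTG2 (5.12 ± 0.20) and in IGFBP3, which binds insulin-like growth factors (4.91 ± 0.18). Each of these 12 genes was higher in 3 of 3 LPS libraries, which the rule for naming them requires. All 12 remained called with the block and without unstimulated replicate 2, as did 1625 and 1623 of all 1625 calls.

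The largest fall was in SERPINB2, plasminogen activator inhibitor 2. It fell by 3.51 ± 0.32 on the log2 scale, from 146 ± 55.4 to 11.4 ± 2.60 TPM (adjusted p = 0.000204). GFI1, a transcriptional repressor of myeloid development, fell by 2.52 ± 0.33, from 22.1 ± 9.11 to 2.83 ± 0.812 TPM. SELPLG, the selectin ligand PSGL-1, fell by 2.41 ± 0.23, from 57.0 ± 12.7 to 9.76 ± 1.37 TPM (adjusted p = 0.000226). MNDA, a nuclear antigen of myeloid cells, fell by 1.93 ± 0.30, BIK, a pro-apoptotic BCL2 family member, fell by 2.13 ± 0.28, and DEPTOR, an inhibitor of mTOR, fell by 2.00 ± 0.25. METTL7B fell by 2.26, TGM5 fell by 2.18, CACNA2D3 fell by 2.18, TTLL1 fell by 2.08, NUDT7 fell by 1.95 and GPA33 fell by 1.94. In all 12 of these genes unstimulated replicate 2 held the lowest of the 3 unstimulated values (for SERPINB2 84.7 TPM in that library). All 3 LPS values lay below it, which the rule for naming these genes requires.

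**Figure D2:**
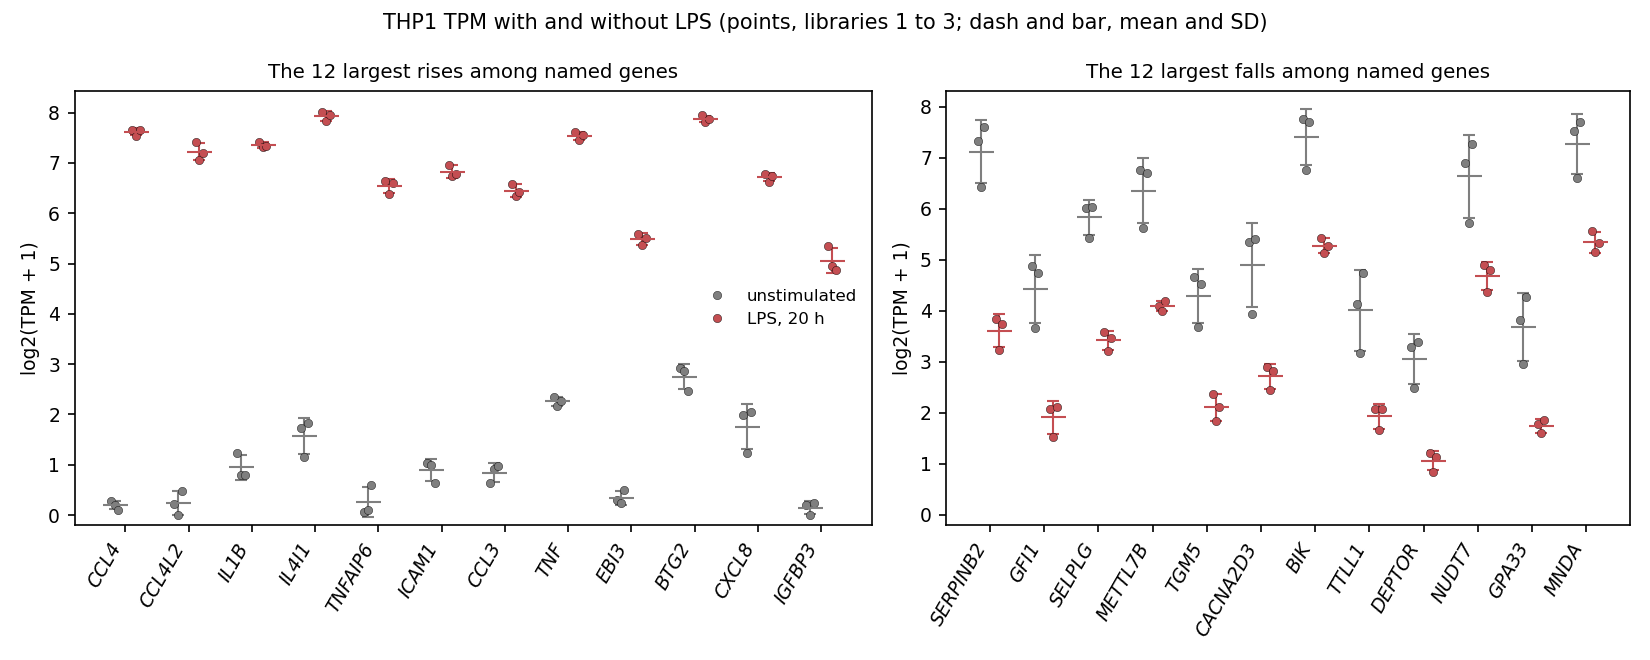
The vertical axes show log2(TPM + 1) for the 12 named genes with the largest rises (left) and falls (right), with a point per library, grey for unstimulated and red for LPS, and a dash and bar for the mean and SD of 3 libraries. The groups do not overlap for any of the 24 genes, by the rule that selected them, with a log2 difference of 7.42 for CCL4 and of -3.51 for SERPINB2.

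NF-kB target genes rose nearly as a whole. Of 24 tested members, 21 rose and 0 fell (23 and 0 when adjusted over the list alone, 23 and 0 with the block, 23 and 0 without unstimulated replicate 2). The NF-kB list had a median log2 difference of 2.17 (over the alternatives 1.03 to 3.38, adjusted p = 5.6e-27 by camera, and adjusted p = 0.185 with an estimated correlation). They included CD83, a marker of activated antigen-presenting cells (4.90 ± 0.21), SOD2, the mitochondrial superoxide dismutase (33.4 ± 13.0 to 799 ± 43.7 TPM), and the inhibitors of the pathway TNFAIP3 (4.27 ± 0.16) and NFKBIA (15.9 ± 5.06 to 143 ± 9.82 TPM). Among 10 tested inflammatory cytokines 6 rose and 0 fell (8 and 0 adjusted over the list alone, 7 and 0 with the block, 8 and 2 without unstimulated replicate 2). The cytokine list had a median log2 difference of 2.15 (over the alternatives 0.31 to 3.75, adjusted p = 2.8e-09 by camera, and adjusted p = 0.261 with an estimated correlation). With no filter, which adds low members to the 10 of 23 tested, its median was 0.31. IL23A, a subunit of interleukin-23, went from 2.46 ± 0.890 to 89.0 ± 2.65 TPM. IL6 was listed at 0 in all 3 unstimulated libraries and at 0.217 ± 0.0467 TPM with LPS, below the filter, and was not tested. Among 17 tested chemokines 16 rose and 0 fell (16 and 0 adjusted over the list alone, 16 and 0 with the block, 16 and 1 without unstimulated replicate 2). The chemokine list had a median log2 difference of 4.30 (over the alternatives 1.55 to 5.31, adjusted p = 1.9e-24 by camera, and adjusted p = 0.185 with an estimated correlation). With no filter, which adds low members to the 17 of 27 tested, its median was 1.55. CCL2, a monocyte attractant, went from 8.26 ± 4.78 to 167 ± 20.5 TPM, and CXCL10, an interferon-induced attractant of T cells, from 0.190 ± 0.0960 to 34.0 ± 7.21 TPM.

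Interferon-stimulated genes rose as a group. Of 32 tested members 21 rose and 0 fell (25 and 0 adjusted over the list alone, 25 and 1 with the block, 25 and 2 without unstimulated replicate 2). The interferon-stimulated list had a median log2 difference of 1.31 (over the alternatives 0.67 to 1.73, adjusted p = 3.6e-17 by camera, and adjusted p = 0.353 with an estimated correlation). The antiviral GTPase gene MX1 went from 2.38 ± 0.796 to 28.2 ± 3.37 TPM. OASL rose by 2.87 ± 0.17, the 2-5A synthetase gene OAS2 by 2.29 ± 0.23 and IFIT1, a sensor of viral RNA ends, by 2.16 ± 0.15. In the list of guanylate-binding proteins and MHC class I presentation, 3 of 20 tested members rose and 2 fell (6 and 3 adjusted over the list alone, 6 and 4 with the block, 7 and 6 without unstimulated replicate 2), and the list was not called (adjusted p = 0.0743 by camera, and adjusted p = 0.679 with an estimated correlation). The risers were GBP2 (2.88 ± 0.21), GBP5 (1.18 ± 0.19) and the peptide transporter gene TAP1 (1.12 ± 0.18). The immunoproteasome subunit gene PSMB8 fell by 1.09 ± 0.23, and NLRC5, the transactivator of MHC class I genes, which was named after its value was seen, fell by 0.67 ± 0.16. Without LPS replicate 1 this list passed the threshold (adjusted p = 0.0464, where the other alternatives except the estimated correlation reached up to 0.247). None of 7 tested MHC class II genes was called with limma, also when adjusted over the list alone, and 0 had an unadjusted p below 0.05. With the block 1 of them was lower, and without unstimulated replicate 2, 3 of the 7 were lower, at a list median of -0.35. In the latter setting the median over all tested genes was -0.24, and the list was not called (adjusted p = 0.410 by camera). In the main model the list was not called, with CD74 at 166 ± 47.4 TPM without and 175 ± 18.8 TPM with LPS and HLA-DRB1 at 146 ± 50.1 TPM without and 119.8 ± 11.4 TPM with LPS (list median -0.034, adjusted p = 0.940 by camera, and adjusted p = 0.976 with an estimated correlation). Without unstimulated replicate 2 HLA-DRB1 fell by 0.54 (adjusted p = 0.00184), and with quantile normalization CD74 was called higher, by 0.31 (adjusted p = 0.0354).

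In the Toll-like receptor pathway 6 of 19 tested members rose and 0 fell (8 and 0 adjusted over the list alone, 8 and 0 with the block, 9 and 3 without unstimulated replicate 2). The Toll-like receptor list had a median log2 difference of 0.45 (over the alternatives 0.19 to 0.60, adjusted p = 0.000390 by camera, and adjusted p = 0.569 with an estimated correlation). TLR4, the LPS receptor, went from 2.76 ± 0.285 to 5.61 ± 0.617 TPM (0.81 ± 0.15, adjusted p = 0.0110). The kinase genes IRAK2 and IKBKE rose by 2.04 ± 0.17 and 1.60 ± 0.19, and the adaptor gene TRAF3 by 1.33 ± 0.17. The LPS co-receptor gene CD14 stood at 4.46 ± 2.18 TPM without and 4.79 ± 0.503 TPM with LPS (0.18 ± 0.30, adjusted p = 0.706), and LY96, which encodes MD-2, at 1.07 ± 0.718 TPM without and 0.265 ± 0.230 TPM with LPS, too low for the test. Signalling feedback inhibitors held 7 risers and 1 faller among 13 tested members (8 and 1 adjusted over the list alone, 8 and 1 with the block, 8 and 1 without unstimulated replicate 2). The feedback inhibitor list had a median log2 difference of 1.06 (over the alternatives 0.49 to 1.19, adjusted p = 5.0e-05 by camera, and adjusted p = 0.365 with an estimated correlation). ZC3H12A, the RNase Regnase-1, rose by 2.77 ± 0.26, the phosphatase genes DUSP6 and DUSP4 by 1.49 ± 0.19 and 1.47 ± 0.16, and ZFP36, which destabilises cytokine mRNA, by 1.47 ± 0.19. The faller, named after its value was seen, was SIGIRR, an inhibitory receptor of the interleukin-1 family, by 1.16 ± 0.19.

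Inducible transcription factors went both ways, with 7 risers and 2 fallers among 19 tested members (8 and 2 adjusted over the list alone, 8 and 2 with the block, 8 and 6 without unstimulated replicate 2). The transcription factor list had a median log2 difference of 0.22 (over the alternatives 0.039 to 0.42, adjusted p = 0.0297 by camera, and adjusted p = 0.574 with an estimated correlation). JUNB rose by 1.43 ± 0.16, JUN by 1.24 ± 0.16 and IRF1 by 1.03 ± 0.16. The fallers, named after their values were seen, were MYC, by 0.86 ± 0.19, and FOSL2, by 0.86 ± 0.17. This list was no longer called without unstimulated replicate 2 (adjusted p = 0.0623), without LPS replicate 2 (0.0721) or without LPS replicate 3 (0.0639), over a range of 0.00049 to 0.174 apart from the estimated correlation. Among monocyte and macrophage surface receptors 9 of 24 rose and 0 fell (10 and 1 adjusted over the list alone, 11 and 1 with the block, 10 and 5 without unstimulated replicate 2). The surface receptor list had a median log2 difference of 0.23 (over the alternatives 0.035 to 0.57, adjusted p = 0.000824 by camera, and adjusted p = 0.574 with an estimated correlation). CD40, a costimulatory receptor, went from 5.48 ± 1.16 to 57.6 ± 7.32 TPM, and CD44, the hyaluronan receptor, from 24.6 ± 2.59 to 134 ± 12.1 TPM. The lectin gene CLEC5A rose by 1.36 ± 0.16 and the formyl peptide receptor gene FPR1 by 1.36 ± 0.19.

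In the list of glycolysis and lactate export 5 of 24 members rose and 0 fell (6 and 2 adjusted over the list alone, 6 and 1 with the block, 10 and 6 without unstimulated replicate 2). The glycolysis list had a median log2 difference of 0.15 (over the alternatives 0.012 to 0.38, adjusted p = 0.0318 by camera, and adjusted p = 0.574 with an estimated correlation). The members that rose were mostly transporters and regulators. The hexose transporter gene SLC2A6 went from 7.61 ± 0.975 to 153 ± 12.1 TPM, the lactate exporter gene SLC16A3 rose by 1.15 ± 0.22 and HIF1A, a transcription factor of the hypoxia response, by 1.42 ± 0.20. The glycolytic enzyme gene PKM went from 249.5 ± 99.4 to 652 ± 41.4 TPM, and SLC2A3, a glucose transporter gene named after its value was seen, rose by 0.93 ± 0.15. The list lost its call with median-of-ratios scaling (adjusted p = 0.0611), without unstimulated replicate 3 (0.194) and without LPS replicate 2 (0.0721), over a range of 0.0037 to 0.199 apart from the estimated correlation. The oxidative phosphorylation list stood lower, with a median log2 difference of -0.25 (over the alternatives -0.57 to -0.036, adjusted p = 0.0387 by camera, and adjusted p = 0.839 with an estimated correlation). Of 32 members 0 rose and 2 fell (0 and 2 adjusted over the list alone, 0 and 3 with the block). In the main model 693 of all 11339 tested genes fell, so this count of fallers lies near the general share. ATP5A1, of the ATP synthase, fell by 0.91 ± 0.22. Without unstimulated replicate 2, 27 of the 32 fell, where 4769 of all 11394 tested genes did (adjusted p = 0.00065 for the list). Without unstimulated replicates 1 or 3 or LPS replicates 1 or 2 the list was not called (0.0739, 0.180, 0.0645 and 0.0721), nor with either scaling (0.0529 and 0.160) or with fry (0.450).

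Among genes of eicosanoid, itaconate and tryptophan metabolism 4 of 17 rose and 1 fell (6 and 1 adjusted over the list alone, 6 and 1 with the block, 6 and 5 without unstimulated replicate 2). The eicosanoid metabolism list had a median log2 difference of 0.35 (over the alternatives 0.17 to 0.51, adjusted p = 0.00976 by camera, and adjusted p = 0.607 with an estimated correlation, and 0.0737 with fry). GCH1, the first enzyme of biopterin synthesis, rose by 1.78 ± 0.19, NAMPT, of NAD salvage, by 1.44 ± 0.18, and the phospholipase gene PLA2G7 by 1.49 ± 0.20. The prostaglandin receptor gene PTGER4 went from 16.2 ± 1.15 to 38.5 ± 5.04 TPM. LTA4H, of leukotriene B4 synthesis, fell by 1.19 ± 0.27 and was named after its value was seen. Extracellular matrix and coagulation genes held 9 risers and 2 fallers among 19 (10 and 2 adjusted over the list alone, 9 and 2 with the block, 11 and 5 without unstimulated replicate 2). The matrix and coagulation list had a median log2 difference of 0.45 (over the alternatives 0.28 to 0.76, adjusted p = 0.000127 by camera, and adjusted p = 0.501 with an estimated correlation). Thrombospondin 1 (THBS1) went from 0.0551 ± 0.0186 to 5.03 ± 0.421 TPM, the collagenase gene MMP1 from 0.0208 ± 0.0183 to 4.36 ± 0.566 TPM and thrombomodulin (THBD) from 11.8 ± 1.17 to 70.4 ± 5.69 TPM. The fallers were SERPINB2 and, named after its value was seen, the metalloproteinase inhibitor gene TIMP2, by 1.27 ± 0.31.

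The list of metallothioneins and metal handling held 5 risers and 1 faller among 15 (8 and 1 adjusted over the list alone, 7 and 1 with the block, 8 and 2 without unstimulated replicate 2). The metal handling list had a median log2 difference of 0.57 (over the alternatives 0.22 to 0.78, adjusted p = 0.000390 by camera, and adjusted p = 0.196 with an estimated correlation). Ferritin heavy chain (FTH1) went from 210.2 ± 23.7 to 2053 ± 10.5 TPM (3.29 ± 0.16, adjusted p = 4.1e-06), while ferritin light chain (FTL), named after its value was seen, stood at 15573 ± 2060.3 TPM without and 16336 ± 1112 TPM with LPS (0.075 ± 0.11, adjusted p = 0.656). Haem oxygenase 1 (HMOX1) rose by 2.05 ± 0.17, the metallothionein gene MT2A by 1.81 ± 0.21 and the transferrin receptor gene TFRC by 1.08 ± 0.24. The iron exporter gene SLC40A1 fell by 0.57 ± 0.16 and the metal transporter gene SLC11A2 rose by 1.00 ± 0.16, both named after their values were seen. The call of SLC40A1 ended with median-of-ratios scaling (-0.46 ± 0.15, adjusted p = 0.0622), where the difference was smaller. Unfolded protein and integrated stress response genes held 5 risers and 0 fallers among 21 (7 and 1 adjusted over the list alone, 7 and 2 with the block, 8 and 5 without unstimulated replicate 2). The stress response list had a median log2 difference of 0.21 (over the alternatives 0.17 to 0.43, adjusted p = 0.0114 by camera, and adjusted p = 0.569 with an estimated correlation). PPP1R15A, which directs dephosphorylation of eIF2 alpha, rose by 1.94 ± 0.21 and DDIT4 by 1.58 ± 0.25, and TRIB3 went from 19.2 ± 5.69 to 44.3 ± 5.32 TPM. The chaperone gene CANX rose by 1.02 ± 0.29, and was not called with median-of-ratios scaling (1.15 ± 0.39, adjusted p = 0.0648, against 0.0458 in the main model and 1.4e-10 without unstimulated replicate 2). Complement and acute phase genes held 6 risers and 0 fallers among 11 (7 and 1 adjusted over the list alone, 6 and 0 with the block, 7 and 3 without unstimulated replicate 2). The complement list had a median log2 difference of 0.64 (over the alternatives 0.11 to 0.85, adjusted p = 0.000760 by camera, and adjusted p = 0.501 with an estimated correlation). With no filter, which adds low members to the 11 of 20 tested, its median was 0.11. The anaphylatoxin receptor gene C3AR1 went from 0.638 ± 0.232 to 14.3 ± 1.85 TPM, and properdin (CFP) from 21.7 ± 3.73 to 46.1 ± 4.19 TPM. PTX3 rose by 1.42 ± 0.16 and S100A12 by 0.98 ± 0.18.

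Several lists held single genes that moved while the list was not called. Among myeloid progenitor and primary granule genes 3 of 18 rose and 2 fell (3 and 4 adjusted over the list alone, 3 and 5 with the block, 4 and 10 without unstimulated replicate 2). The myeloid progenitor list had a median log2 difference of -0.34 (over the alternatives -0.45 to -0.13, adjusted p = 0.160 by camera, and adjusted p = 0.674 with an estimated correlation). MYB, a transcription factor of progenitors, fell by 1.64 ± 0.22 and GFI1, named above, fell by 2.52 ± 0.33. SPI1, which encodes PU.1, rose by 1.02 ± 0.27. The granule protein gene AZU1 rose by 1.59 ± 0.44. Its call ended with median-of-ratios scaling (1.71 ± 0.58, adjusted p = 0.0643, against 0.0461 in the main model and 5.0e-14 without unstimulated replicate 2, which held 376 TPM). HOXA9, named after its value was seen, rose by 0.81 ± 0.19. In the inflammasome list 1 of 12 rose and 2 fell (1 and 3 adjusted over the list alone, 1 and 3 with the block, 2 and 7 without unstimulated replicate 2). The inflammasome list had a median log2 difference of -0.34 (over the alternatives -0.58 to -0.021, adjusted p = 0.650 by camera, and adjusted p = 0.864 with an estimated correlation). NINJ1, which ruptures the membrane of dying cells, went from 33.9 ± 5.75 to 266 ± 11.8 TPM, the adaptor gene PYCARD fell by 0.97 ± 0.25 and the sensor gene NAIP fell by 1.09 ± 0.22.

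Among 32 cell cycle genes 3 rose and 3 fell (3 and 4 adjusted over the list alone, 3 and 5 with the block). The cell cycle list had a median log2 difference of -0.29 (over the alternatives -0.47 to -0.10, adjusted p = 0.432 by camera, and adjusted p = 0.864 with an estimated correlation). CCNE2, a cyclin of the entry into S phase, rose by 1.36 ± 0.19, the ribonucleotide reductase gene RRM2 by 1.13 ± 0.18 and the mitotic kinesin gene KIF11 by 0.89 ± 0.19. The mitotic gene CENPF fell by 0.92 ± 0.25, and MCM5 and CDC20, named after their values were seen, fell by 0.71 ± 0.20 and 0.65 ± 0.14. Without unstimulated replicate 2, 4 rose and 17 fell, where 2060 of all 11394 tested genes were higher and 4769 lower. The list was not called there (adjusted p = 0.410 by camera, range over the other alternatives except the estimated correlation 0.319 to 0.653). Of 22 cholesterol synthesis genes 5 rose and 1 fell (5 and 2 adjusted over the list alone, 5 and 3 with the block, 6 and 7 without unstimulated replicate 2), with the sterol carrier gene STARD4 higher by 1.24 ± 0.18 and MVD by 0.84 ± 0.19, while FDFT1, squalene synthase, fell by 0.85 ± 0.23. Camera did not call the list (adjusted p = 0.479 by camera, and adjusted p = 0.864 with an estimated correlation). CYP51A1 and HMGCS1, named after their values were seen, rose by 0.82 ± 0.22 and 0.68 ± 0.15. Of 11 lipid efflux and LXR target genes 2 rose and 0 fell (2 and 2 adjusted over the list alone, 2 and 2 with the block, 3 and 4 without unstimulated replicate 2, adjusted p = 0.432 by camera, and adjusted p = 0.839 with an estimated correlation). Lipoprotein lipase (LPL) went from 19.0 ± 1.24 to 80.5 ± 4.43 TPM and the cholesterol exporter gene ABCA1 from 1.72 ± 0.507 to 3.17 ± 0.400 TPM. ABCA1 was not called with median-of-ratios scaling (0.70 ± 0.22, adjusted p = 0.0544, against 0.63 ± 0.18 and 0.0490 in the main model). Quantile normalization ended these 3 calls too: AZU1 1.76 ± 0.59 (adjusted p = 0.0593), CANX 1.23 ± 0.41 (0.0575) and ABCA1 0.64 ± 0.21 (0.0545). In each of the 3 genes and both settings the difference grew, and the call ended because the standard error grew more. Among genes named after their values were seen, CYP51A1 lost its call with quantile normalization (0.90 ± 0.29, adjusted p = 0.0552) and CDC20 with median-of-ratios scaling (-0.52 ± 0.17, adjusted p = 0.0595). In the cholesterol and LXR lists the median (-0.019 and -0.055) was negative while the mean (0.056 and 0.15) and the direction of camera were positive.

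**Figure D3:**
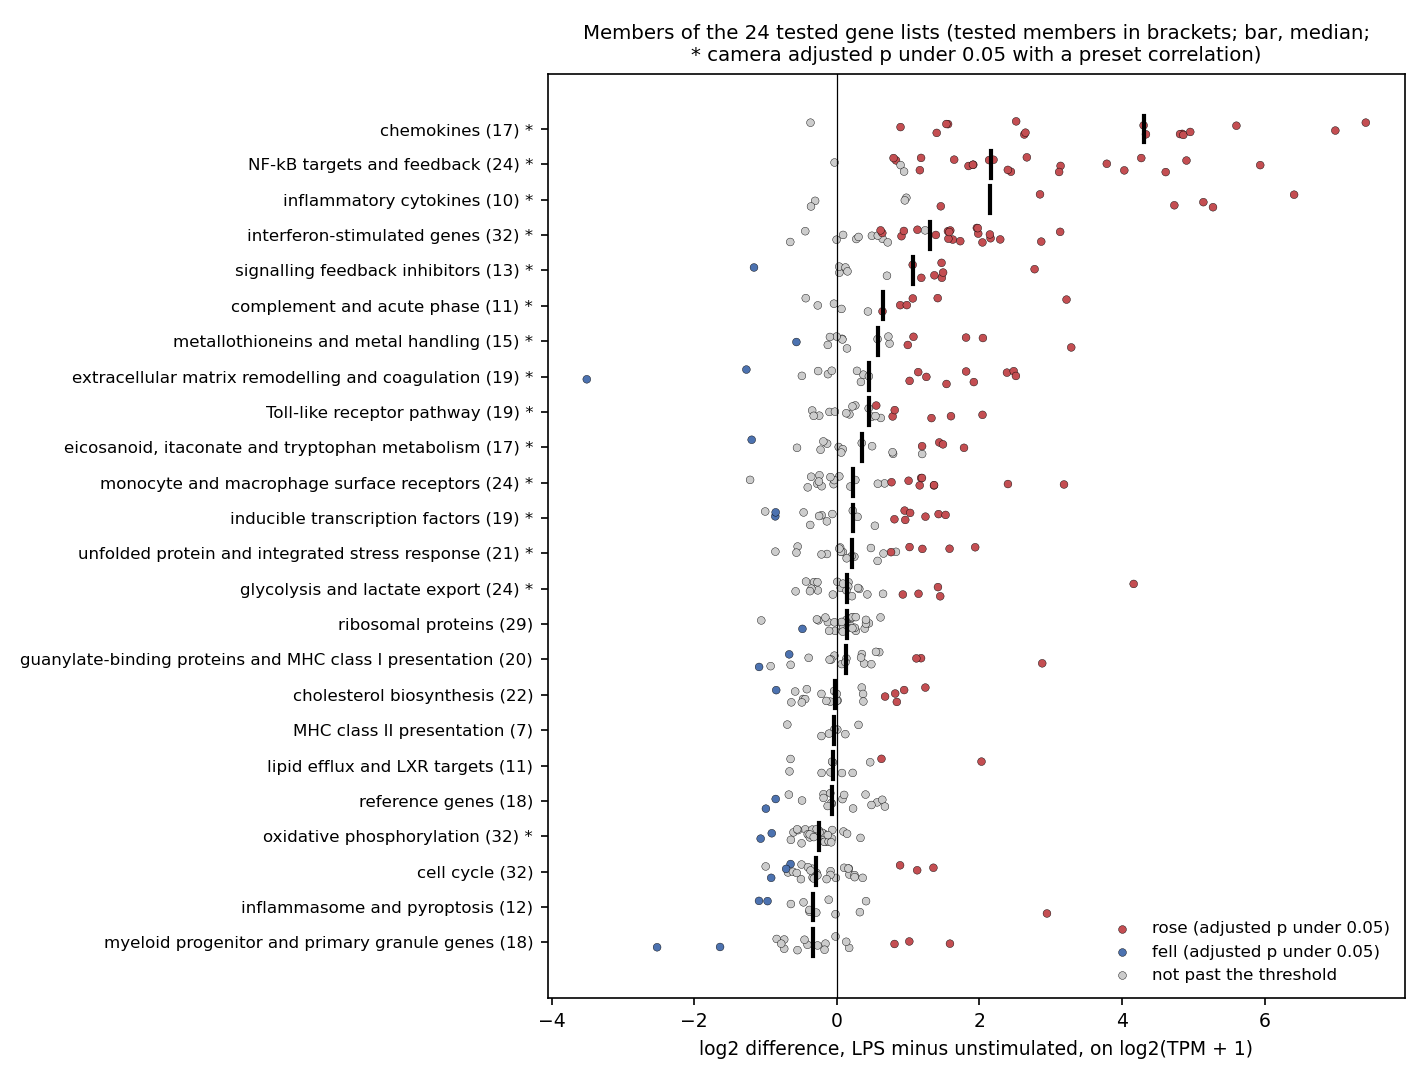
The horizontal axis shows the log2 difference, LPS minus unstimulated, on log2(TPM + 1), with a point for each tested member of the 24 tested lists, red for called rises, blue for called falls and grey for genes not past the threshold, and a bar at the list's median. The chemokine list has the highest median (4.30) and the myeloid progenitor list the lowest (-0.34), and a star marks lists called by camera with the preset correlation.

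Of 18 reference genes often used for normalisation 0 rose and 2 fell (1 and 2 adjusted over the list alone, 2 and 3 with the block, 5 and 7 without unstimulated replicate 2), with a median of -0.074, a mean of -0.032 and camera's direction upward (adjusted p = 0.728 by camera, and adjusted p = 0.851 with an estimated correlation). GAPDH stood at 3772 ± 569.9 TPM without and 4119 ± 292 TPM with LPS (0.14 ± 0.14, adjusted p = 0.519). ACTB stood at 8636 ± 4784 TPM without and 11662 ± 1464 TPM with LPS (0.57 ± 0.32, adjusted p = 0.242), with 14048 TPM in unstimulated replicate 2 against 6888 and 4971 TPM in replicates 1 and 3. Without that replicate both were called higher, ACTB by 0.99 ± 0.092 (adjusted p = 8.1e-11) and GAPDH by 0.25 ± 0.085 (adjusted p = 0.0109). These p values lean on the prior variance, as stated above for that setting. RPL13A, which shares reads with the pseudogene RPL13AP5, fell by 0.86 ± 0.18. Of 29 ribosomal protein genes 0 rose and 1 fell (0 and 0 adjusted over the list alone, 0 and 2 with the block). The ribosomal protein list had a median log2 difference of 0.14 (over the alternatives -0.00029 to 0.54, adjusted p = 0.227 by camera, and adjusted p = 0.839 with an estimated correlation). The faller was RPL7, by 0.48 ± 0.11, and its call ended with median-of-ratios scaling (-0.36 ± 0.17, adjusted p = 0.151, against 0.0237), where the difference was smaller and its standard error larger. Quantile normalization ended it as well (-0.53 ± 0.18, adjusted p = 0.0631), with a larger difference and a larger standard error. RPS6 stood at 11672 ± 1039 TPM without and 11386 ± 388 TPM with LPS. Without unstimulated replicate 2, 19 ribosomal protein genes rose and 5 fell and the list was called higher (adjusted p = 0.00029, range over the other alternatives except the estimated correlation 0.00190 to 0.739).

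Few markers of other cell types were abundant enough for the test. Of 14 erythroid markers 1 was tested, EPOR, at 2.98 ± 0.489 TPM without and 1.95 ± 0.270 TPM with LPS (adjusted p = 0.106), and TAL1 stood at 0.0945 ± 0.0380 TPM without and 0.120 ± 0.125 TPM with LPS. Among T and NK cell markers GNLY went from 1.03 ± 0.617 to 3.38 ± 0.656 TPM (adjusted p = 0.0180) and NKG7 stood at 50.1 ± 19.2 TPM without and 42.9 ± 3.71 TPM with LPS (adjusted p = 0.776), both granule protein genes. Of the 14 markers of that list 11 were listed, and no other listed one was abundant enough for the test. The abundance of the unlisted ones is unknown. The B cell gene CD79B stood at 1.73 ± 0.490 TPM without and 0.796 ± 0.368 TPM with LPS and was not called, although it was lower with the block (adjusted p = 0.0218, against 0.0762 without it). Of the epithelial markers KRT8 stood at 2.08 ± 0.564 TPM without and 1.34 ± 0.490 TPM with LPS and KRT18 at 0.264 ± 0.199 TPM without and 0.278 ± 0.0903 TPM with LPS. Counted over each list alone, 1 erythroid and 1 B cell gene were lower, 1 T and NK cell gene was higher, and 0 epithelial genes changed. Each list held only 1 or 2 tested genes, so this adjustment is slight. For EPOR, the only tested erythroid gene, it is none (limma, unadjusted p = 0.0268). Without unstimulated replicate 2, 4 of these genes were called lower: EPOR (adjusted p = 0.00532), NKG7 (0.00719), CD79B (0.00465) and KRT8 (0.0262). So were 4769 of all 11394 genes tested in that setting. EPOR was also called lower with quantile normalization (0.0329). These lists had fewer than 3 tested members and were not tested as lists.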

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

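No result changed direction while called under any alternative. Pseudocount 0.1, the robust or untrended prior variance and removal of the mitochondrial rRNAs left the 3 counts within 1.5 times and every list on its side of the threshold. The tests with the 100-gene share as a covariate, the block with median-of-ratios scaling, and that scaling without unstimulated replicate 2 were chosen after the data were examined. Why the counts moved was not tested. Fewer libraries leave fewer degrees of freedom and stricter filters test fewer genes, but neither can account for counts that grew. The main model had 4 residual degrees of freedom. Without unstimulated replicate 2 there were 3, with 2060 genes higher and 4769 lower. The block left 2, with 1326 and 1699.

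The count of higher genes (932) was 565 with a mean of at least 5 TPM, 1706 with median-of-ratios scaling, 1526 with quantile normalization, 2926 with library weights, 2449 with the covariate, 1761 with the block and median-of-ratios scaling together, and 3437 with that scaling without unstimulated replicate 2. The count of lower genes (693) was 370 with a mean of at least 5 TPM, 291 with no filter, 1508 with median-of-ratios scaling, 1901 with quantile normalization, 5834 with library weights, 1969 with the covariate, 1559 with the block and median-of-ratios scaling together, and 3430 with that scaling without unstimulated replicate 2. The count changed at least 2-fold (744) was 493 with a mean of at least 5 TPM, 294 with a pseudocount of 5, 1436 with library weights, and 1335 with median-of-ratios scaling without unstimulated replicate 2. Without one library at a time the counts ran from 344 to 2060 higher, from 99 to 4769 lower and from 401 to 1594 changed at least 2-fold, each highest without unstimulated replicate 2.

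With the replicate block 1326 genes were higher, 1699 lower and 806 changed at least 2-fold. The count of lower genes was the only count it moved by over 1.5 times, CD79B was the only named gene it added to the calls, and it changed no other call of a list or named gene.

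With an estimated correlation none of the 15 lists called by camera kept its call, at the same medians (NF-kB targets 2.17, cytokines 2.15, chemokines 4.30, interferon-stimulated genes 1.31, Toll-like receptor pathway 0.45, feedback inhibitors 1.06, inducible transcription factors 0.22, surface receptors 0.23, glycolysis 0.15, oxidative phosphorylation -0.25, eicosanoid metabolism 0.35, matrix and coagulation 0.45, metal handling 0.57, stress response 0.21, complement 0.64). With fry oxidative phosphorylation (-0.25) and eicosanoid metabolism (0.35) lost theirs. A mean of at least 5 TPM ended the calls of inducible transcription factors (median 0.042), surface receptors (0.035) and eicosanoid metabolism (0.21). Glycolysis and oxidative phosphorylation lost theirs with median-of-ratios scaling (0.27 and -0.12), quantile normalization (0.18 and -0.14) and the covariate (0.10 and -0.036), and glycolysis with library weights (0.012). Inducible transcription factors also lost the call with the covariate (0.33), the block with median-of-ratios scaling (0.33) and that scaling without unstimulated replicate 2 (0.35), where eicosanoid metabolism lost it too (0.51). Ribosomal proteins were called higher with library weights (0.15) and with median-of-ratios scaling without unstimulated replicate 2 (0.54), and myeloid progenitor genes lower with the covariate (-0.21). Without one library at a time the medians ran from -0.57 to -0.13 for oxidative phosphorylation, from 0.093 to 0.18 for glycolysis, from 0.039 to 0.42 for inducible transcription factors, from -0.00029 to 0.25 for ribosomal proteins and from 0.073 to 0.21 for guanylate-binding proteins and MHC class I. Over 2191 pairs of a named gene and an alternative, 2031 kept their side of the threshold, 133 lost the call and 27 gained it. Median-of-ratios scaling and quantile normalization each ended 4 calls, of AZU1, CANX, ABCA1 and RPL7. Leaving out unstimulated replicates 1 and 3 ended 20 and 13 calls, and leaving out LPS replicates 1, 2 and 3 ended 28, 23 and 23. Read depth, which limits low genes, is unknown.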

Other observations

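Among called genes outside the lists, chosen after their values were seen, several rises matched the named ones in size. STAT4, a signal transducer of interleukin-12, went from 0.592 ± 0.156 to 31.5 ± 3.94 TPM (4.35 ± 0.17, limma adjusted p = 1.0e-06), the protease inhibitor gene SERPINE2 from 4.13 ± 1.15 to 78.5 ± 4.42 TPM, and the interleukin-10 receptor gene IL10RA from 3.29 ± 0.559 to 58.2 ± 4.94 TPM. IL7R went from 0.285 ± 0.159 to 14.6 ± 2.55 TPM, the adenosine receptor gene ADORA2A from 0.0608 ± 0.0817 to 11.4 ± 2.44 TPM, the Notch ligand gene DLL4 from 0.553 ± 0.00957 to 7.90 ± 0.525 TPM and aromatase (CYP19A1) from 0.308 ± 0.116 to 6.27 ± 0.709 TPM. In lipid metabolism the fatty acid ligase gene ACSL1 went from 12.6 ± 1.21 to 144 ± 12.5 TPM and malic enzyme 1 (ME1) from 3.31 ± 0.310 to 41.0 ± 3.12 TPM. Each was higher in 3 of 3 LPS libraries, as was every gene called higher in the main model. Each was also called with the block, with median-of-ratios scaling and without unstimulated replicate 2, as were nearly all calls.

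Among the falls, the chemokine receptor gene CXCR2 went from 23.7 ± 6.04 to 7.99 ± 0.399 TPM, the leukotriene receptor gene CYSLTR1 from 15.8 ± 4.65 to 4.99 ± 1.16 TPM and the mitophagy kinase gene PINK1 from 13.2 ± 7.31 to 3.03 ± 0.575 TPM. The noncoding RNAs CCDC26 and LINC00977, whose genes lie on the same chromosome arm as MYC, fell by 1.76 ± 0.44 and 1.72 ± 0.39, from 30.5 ± 17.8 to 7.13 ± 1.34 TPM and from 12.1 ± 6.42 to 2.62 ± 0.794 TPM, and MYC itself went from 84.2 ± 7.89 to 46.0 ± 4.91 TPM. PVT1, the neighbour of MYC, stood at 4.32 ± 1.02 TPM without and 3.88 ± 0.875 TPM with LPS and was not called (adjusted p = 0.700). Of 78 symbol families with at least 15 tested genes, tested with camera after the data were examined, those opening with IL (median 0.68, 14 of 28 risen, adjusted p = 2.0e-05) were higher and those opening with MRPL, the large subunit of the mitochondrial ribosome (median -0.51, 2 of 49 fallen, adjusted p = 0.0492), were lower. With an estimated correlation the adjusted p was 0.992 for both. Over all 11339 tested genes 932 were higher and 693 lower, so the 2 fallen MRPL genes do not exceed the general share. The set of called families moved with the settings: 4 were called with the block, 3 with median-of-ratios scaling and 6 without unstimulated replicate 2. Those opening with MRPS, the small subunit of the mitochondrial ribosome (median -0.46), were lower in all 3 of these (adjusted p = 0.0258, 0.0158 and 0.00123, against 0.0837 in the main model). Those opening with RPS (median 0.22) were higher with the block (0.0259) and without unstimulated replicate 2 (3.0e-06), against 0.0837. With an estimated correlation 0 of the 78 families were called, with an adjusted p of 0.992 for MRPS and RPS too. Median-of-ratios scaling left the directions of IL and MRPL (medians 0.79 and -0.39).

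The tests of LPS exposure and of length and GC content in unstimulated replicate 2, and of scaling for SERPINB2, were chosen after the result was seen. Unstimulated replicate 2 departed from replicates 1 and 3. Exposure to LPS or reads from an LPS library would put part of the LPS rise into it, and over 45 NF-kB, cytokine and chemokine genes the median share of the rise present was -0.0176 (bootstrap interval -0.0372 to -0.0047). The bootstrap resampled genes within this single library, so the interval gives the spread over genes. The TPM were not scaled, and the median-of-ratios factor was 0.838 in this library against 1.17 and 1.18 in replicates 1 and 3. This lowers the share, so a small admixture could be masked. A fit on transcript length, GC content and abundance took up 8.69% of its variance. A difference in culture, in RNA handling or in library preparation may stand behind it and remains open, and no biological explanation was tested, since the labels give none.

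SERPINB2 fell with LPS, although it is known as a gene that LPS induces in monocytes. Reads shifted to related genes would leave the family's total in place, but the summed TPM of 13 SERPINB genes fell by 1.60 on the log2 scale, and the 12 others together went from 138.4 to 78.7 TPM. With median-of-ratios scaling the difference was -3.39. The factors of that scaling ran only from 0.838 to 1.18, too narrow to make or remove a fall of this size, so this outcome was given in advance. Other explanations were not tested. A change in SERPINB2 transcripts after 20 h of LPS is a hypothesis found and tested on the same libraries, and no earlier time was measured here.

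FTH1 rose while FTL, the other ferritin subunit, did not pass the threshold. Reads shared with pseudogenes could produce such a rise only if the pseudogenes lost TPM, but the summed TPM of FTH1 and its 2 listed pseudogenes rose by 3.29 on the log2 scale, and the pseudogenes themselves held 1.39 TPM without and 3.36 TPM with LPS. Ferritin pseudogenes that the tables do not list stay open as a source. The difference between the subunits was not tested, and no biological explanation was tested.

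The 6 libraries can be split into groups of 3 in 10 ways, too few for a share below 0.05. The real split gave 1625 called genes and 744 changed at least 2-fold, the highest of the other splits gave 0 and 0, and 1 of 10 splits, the real one, was as large in each case. Of the 4 splits that part all 3 numbered pairs, the other 3 gave 0 calls. Every split but the real one mixes LPS and unstimulated libraries in both groups. The LPS difference then enters the spread within groups, so few calls can arise there. The comparison of splits therefore does not decide whether the calls differ from chance.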
